A study of Homo sapiens with 8 samples.

How the data were processed

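Guide cassettes were amplified from genomic DNA of K562 cells and sequenced, per the labels' protocols, in 8 libraries. Groups were taken from the sample titles, which give the arm (sgDDX3 or sgGal4), the time point (initial or final) and the replicate, so that each of 4 groups held 2 libraries, and the labels give 50 ng/ml doxycycline for all. The number of cell doublings between the time points and the promoters of the constructs are not given in the sources used here.

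The deposited count files hold whole-number read counts per guide, not normalized, with 209070 guides each. The aligner or counter and its version are not given in the sources used here. The authors' guide tables hold log2 growth values (gamma, final over initial), per the file headers, and their log2 scale was checked against the counts, on which they had a slope of 1.01 in both arms. The authors' gene tables hold, per the file headers, the mean log2 value of the strongest 3 guides and a Mann-Whitney p-value for each of 20524 targets, beside 20524 pseudo-genes that the authors drew. The authors' library table ties 104535 guides to genes and start sites, 5 per target, of which 1895 are non-targeting. Guides outside this table took 0.627% to 0.652% of the counts and were left out of the library sizes and tests.

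Guides with a mean count of at least 50 over the 4 initial libraries were kept, 102179 in all with 1841 non-targeting. Each library was scaled to its total over non-targeting guides, and a target's score was the mean over its guides, at least 3, of log2(scaled count + 1), minus the median over non-targeting guides. Fold changes are therefore on the log2(count + 1) scale, which understates the loss of guides with few counts. Scores of 20514 of 20528 targets were tested with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend and robust) in R 4.3.3 with statmod 1.5.0, on group means of all 8 libraries, which share an estimate of the spread with 4 residual degrees of freedom. The contrasts were final minus initial in each arm, the difference of these between arms, the same difference with the sgGal4 effect multiplied by the slope between arms, and the difference of the initial groups. The slope was that of the first principal axis through the origin over the genes of the proteasome, spliceosome and replication lists, with an interval from 10000 resamples of genes. P-values were adjusted by Benjamini-Hochberg over all targets, at a threshold of 0.05, and tests were two-sided. Guide counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood, library sizes set to non-targeting totals).

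Pseudo-genes, 2000 random sets of non-targeting guides, went through the same fit outside the adjustment. The plan set 10 guides each, and sets of 5 were added after the library table was seen to hold 5 guides per target. The number of false calls to allow for is the share of 5-guide sets called times the number of targets tested.

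The 28 gene lists were fixed before the data were examined and tested with camera on 1 primary target per gene (the start site marked P1P2, else P1, else the earliest in alphabetical order), with a preset correlation of 0.01 and, beside it, an estimated correlation. They were the large and small ribosomal subunit proteins, the small-subunit processome, eIF3, eIF4F and poly(A)-binding proteins, ternary complex and elongation factors, aminoacyl-tRNA synthetases, the 26S proteasome, the spliceosome core, TREX and mRNA export, nonsense-mediated decay, the nuclear exosome, CCR4-NOT and cytoplasmic decay, the nuclear pore, other DEAD-box helicases, stress granule proteins, the integrated stress response, RIG-I-like receptor signalling, ribosome quality control, mTORC1 activators, negative regulators of RAS, mTORC1 and JAK-STAT signalling, DNA replication, condensin and cohesin, mitochondrial ribosomal proteins, respiratory complex I, BCR-ABL and erythroid-leukaemia regulators, 3-prime end processing with Integrator, and olfactory receptors as a control.

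The named genes followed a rule fixed at the same time. It took DDX3X always. For each growth effect it took the 6 lowest and 6 highest called primary targets with the same sign in both replicates, and from each list the called member with the largest change, or the largest 2 where at least 10 were called. For the scaled difference it took up to 12 called targets at each end, of which there were none, and for the unscaled and initial differences up to 4 at each end. Neighbours, genes whose annotated spans come within 1000 bp of each other on either strand, fall outside the rule. So do genes named as having been chosen after their values were seen. Distances between start sites were not measured. Neighbours were found by gene symbol in a RefSeq table, in which 18805 of 18894 library genes were matched, 1373 by an older symbol. No guide coordinates were used, since the build of the guide positions is not given in the sources used here. Guides with a sequence shared by another target, 2762 in all, touch 862 targets.

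The alternatives were other scalings (TMM, DESeq2 1.42.0 size factors, total counts), a pseudocount of 10, minimum initial counts of 1 and 200, the median over guides, other slopes and a curved scale, summed counts per target tested with edgeR or DESeq2, a Mann-Whitney test against non-targeting guides, a further limit from pseudo-genes, replicate blocks, and leaving out each library. Fits with a spread of its own for each group, the 4 libraries of an arm alone and the limit from 5-guide pseudo-genes were added after the data were seen. The restriction to the 5 top-ranked guides changes nothing, since the library table holds 5 guides per target.

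limma, edgeR and camera were tried on simulated data with the means and library sizes of these libraries and a single spread per group. The simulated spread did not fall with guide abundance, all guides of a target changed alike, and the scaled difference took the slope as known. The shares called may therefore not carry over to these libraries. The Mann-Whitney and DESeq2 tests were not simulated. limma called 95% of targets with a true change of -1 in the sgGal4 arm and 75% in the sgDDX3 arm, 0% and 10% of those at -0.5, and at most 5 of 20314 unchanged targets in any contrast. edgeR called 29.0% of guides with a true change of -2 in the sgGal4 arm and 33.7% in the sgDDX3 arm. camera gave a p under 0.05 for 8 of 200 unchanged lists, and a simulated slope of 0.5 was recovered as 0.483. Total counts per library, from 43362293 to 76808768, are PCR reads without molecular identifiers and not independent molecules, so the spread between replicates, not counting error, sets the precision. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.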

Results

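Genome-wide CRISPR interference growth screens were run in K562, an established myelogenous leukaemia line, in a background that carried a guide against DDX3X (the sgDDX3 arm) or a control guide against Gal4, a yeast transcription factor (the sgGal4 arm). In such a screen each cell also receives a library guide that directs a dead Cas9 repressor to the start site of a gene, and guides whose knockdown slows growth become rarer over time. DDX3X encodes an RNA helicase of the DEAD-box family that acts in translation initiation, and the screens ask which knockdowns affect growth differently when it is targeted as well. Each arm was sampled at an initial and a final time point with 2 replicates, giving 8 libraries in 4 groups of 2, all grown with 50 ng/ml doxycycline. Guide cassettes were amplified from genomic DNA and counted.

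Total counts ran from 43362293 in replicate 1 of the initial sgGal4 group to 76808768 in replicate 2 of the initial sgDDX3 group, and the median count per guide from 382 to 680. Non-targeting guides took 1.75% to 1.86% of the counts and no guide took more than 0.0104%. Of 104535 guides, 102179 had a mean initial count of at least 50 and were kept, which left 20514 targets (a gene's annotated start site, with up to 5 guides) of 18894 genes. The score of a target was its guides' mean log2 count relative to non-targeting guides, and its growth effect was the final minus the initial score, so that lost guides have negative values. Replicates differed by more than counting noise, with a chi-square per degree of freedom from 7.45 to 63.6. The final sgDDX3 libraries differed most, with an SD of the replicate difference over non-targeting guides of 0.788, against 0.455 in the final sgGal4 libraries and 0.290 and 0.318 in the initial sgDDX3 and sgGal4 libraries. Across targets, which are not independent replicates, the growth effects of replicates 1 and 2 correlated with r = 0.398 in the sgDDX3 arm and 0.860 in the sgGal4 arm. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries.

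Library guides against DDX3X itself lost representation in both arms. The DDX3X score was 0.05 and 0.09 in the initial and -0.92 and -1.06 in the final sgGal4 libraries, and 0.21 and -0.02 in the initial and -1.04 and -0.87 in the final sgDDX3 libraries. Its growth effect was -1.06 ± 0.14 (SE, n = 2 libraries per time point, limma adjusted p = 0.000286) in the sgGal4 arm and -1.05 ± 0.14 (limma adjusted p = 0.0021) in the sgDDX3 arm. Each SE comes from the spread shared by all 8 libraries, so a target has the same SE in either arm. The SD of target scores between final replicates was 0.257 in the sgDDX3 arm and 0.152 in the sgGal4 arm. The arms' effects differed by 0.01 ± 0.20 (limma adjusted p = 0.995), and the initial scores by 0.03 ± 0.14 (limma adjusted p = 1.00). The same guides did not lead in both arms, since a guide at -0.11 in the sgGal4 arm was at -2.01 in the sgDDX3 arm, and another at -1.39 was at 0.00. The latter value averages sgDDX3 replicates that went opposite ways, with counts of 712 and 888 initially and 1145 and 472 at the end. Guide counts in genomic DNA do not measure DDX3X RNA, so they do not check the knockdown that names the sgDDX3 arm. The call of DDX3X in the sgDDX3 arm was lost in 4 of 24 alternative settings. They were that arm fitted alone (adjusted p = 0.0528), the fit without replicate 1 of the initial sgDDX3 group (adjusted p = 0.108), the median over guides (-0.79, adjusted p = 0.153) and the Mann-Whitney test (adjusted p = 0.193).

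**Figure D1:**
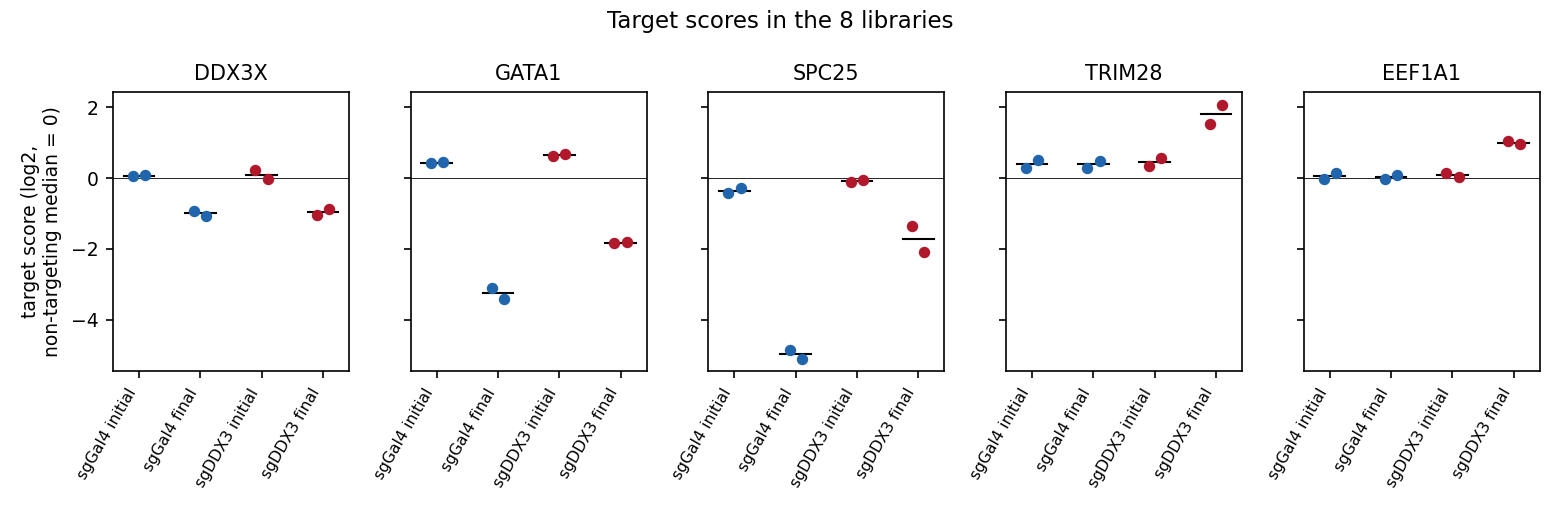
Target scores (log2, non-targeting median at 0) of DDX3X, GATA1, SPC25, TRIM28 and EEF1A1 in the 8 libraries, with a point per library, a bar at each group mean, sgGal4 in blue and sgDDX3 in red. DDX3X ends at -0.92 and -1.06 in the sgGal4 arm and at -1.04 and -0.87 in the sgDDX3 arm, where TRIM28 rises by 1.34 and EEF1A1 by 0.92.

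The sgGal4 arm shows what K562 cells need for growth without a second targeted gene. The lowest growth effects were those of SPC25, a kinetochore protein (-4.62 ± 0.26), the spliceosomal helicase AQR (-4.28 ± 0.42), the splicing factor SMU1 (-3.86 ± 0.35), CDC20, which activates the anaphase-promoting complex (-3.81 ± 0.38), the mitotic kinase AURKB (-3.77 ± 0.25) and the nuclear pore protein NUP205 (-3.76 ± 0.19). The erythroid transcription factor GATA1 (-3.69 ± 0.17) and GAB2, an adaptor in BCR-ABL signalling (-3.15 ± 0.26), fell as well. Guides gained for AMBRA1, which targets cyclin D for degradation (0.56 ± 0.10), the cyclin-dependent kinase inhibitor CDKN1C (0.53 ± 0.14), ARRDC3 (0.52 ± 0.11), MAP4K5 (0.47 ± 0.12), STAT5A (0.47 ± 0.10) and LZTR1, which limits RAS (0.45 ± 0.12). Each of these 6 gains lost its call in 3 to 7 of 24 alternative settings. The gene STAT5A lies within 1000 bp of STAT5B, whose own guides fell by 1.33. Random sets of 5 non-targeting guides give 30.8 false losses and 0 false gains as the number to allow for, from 3 and 0 of 2000 sets. As 1 set stands for 10.3 targets, 0 sets cannot show that the gains are free of false calls. In all, 1420 targets fell and 8 rose at an adjusted p under 0.05 (limma). The count ran from 873 without replicate 1 of the initial sgGal4 group to 2196 without replicate 2 of the final sgDDX3 group.

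The ribosomal, ribosome assembly, initiation, elongation and aminoacylation lists shifted lower in the sgGal4 arm by camera, with a preset or an estimated correlation between genes. Of 47 large ribosomal subunit proteins 42 fell (42 adjusted over the list alone, median -1.53), led by RPL17 (-3.26) and RPL6 (-3.16). Of 32 small ribosomal subunit proteins 31 fell (31 adjusted over the list alone, median -1.60), led by RPS27A (-2.77) and RPS4X (-2.73). Among small-subunit processome and rRNA processing factors 33 of 47 fell (39 adjusted over the list alone, median -0.72), with HEATR1 and FBL both at -1.93. Of 13 eIF3 subunits 9 fell (10 adjusted over the list alone, median -1.20), with EIF3A at -2.70. Of 25 ternary complex, subunit joining and elongation factors 14 fell (15 adjusted over the list alone, median -0.56), among them EIF2S1 (-2.29) and EEF2 (-1.89). Of 20 cytosolic aminoacyl-tRNA synthetases 16 fell (17 adjusted over the list alone, median -1.03), led by SARS (-3.23) and AARS (-2.31). Of 15 eIF4F and poly(A)-binding proteins 4 fell (4 adjusted over the list alone, median -0.18), led by EIF4G2 (-2.41), a homologue of EIF4G1 that does not bind the cap-binding protein. That list passed with the preset correlation (camera adjusted p = 0.00835) and not otherwise (adjusted p = 0.0587 with an estimated correlation).

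The lists of nuclear RNA processing, replication and protein turnover also shifted lower in the sgGal4 arm under both settings of the correlation. Of 56 spliceosome core genes 52 fell (54 adjusted over the list alone, median -2.23). Of 49 DNA replication genes 40 fell (45 adjusted over the list alone, median -1.30, GINS1 at -3.65 and RPA2 at -3.45). Of 32 proteins of the 26S proteasome 28 fell (29 adjusted over the list alone, median -1.78, PSMC4 at -3.36 and PSMB6 at -3.12). Of 35 genes of TREX, the exon junction complex and mRNA export 18 fell (19 adjusted over the list alone, median -0.53), led by the exon junction proteins RBM8A (-3.48) and EIF4A3 (-2.46). Of 30 nuclear pore complex genes 16 fell (18 adjusted over the list alone, median -0.62), NUP62 at -3.14. Of 35 genes of 3-prime end processing and Integrator 17 fell (20 adjusted over the list alone, median -0.44). INTS2 stood at -2.44 and CSTF1, a gene within 1000 bp of AURKA (-2.18), at -2.01. Of 26 genes of the nuclear exosome and its PABPN1, PAXT and NEXT cofactors 10 fell (13 adjusted over the list alone, median -0.39), with SRRT at -1.90 and EXOSC2 at -1.23. Among 38 DEAD-box helicases other than DDX3X 14 fell (18 adjusted over the list alone, median -0.27), with DDX23, a spliceosomal helicase, at -2.29. Of 21 condensin and cohesin genes 11 fell (13 adjusted over the list alone, median -0.52), with SMC2 at -2.46 and SMC1A at -2.51, the latter sharing 2 of its 5 guides with RIBC1. Of 75 mitochondrial ribosomal proteins 59 fell (70 adjusted over the list alone, median -0.81, MRPL13 at -1.82 beside its neighbour MTBP at -1.52, MRPL16 at -1.70). Of 50 genes of respiratory complex I 6 fell (7 adjusted over the list alone, median -0.23). The gene NDUFA2 (-2.12) lies within 1000 bp of IK (-3.35).

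In the sgGal4 arm, of 36 BCR-ABL signalling and erythroid-leukaemia regulators 13 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.32). Of 24 mTORC1 activators 10 fell (14 adjusted over the list alone, median -0.39), led by SEC13 (-1.48), which also serves the nuclear pore and vesicle coats, and MTOR (-1.46). Both lists held under either correlation. Of 18 ribosome quality control genes 7 fell (8 adjusted over the list alone, median -0.29), led by VCP (-3.39), an ATPase with many other roles. Of 13 nonsense-mediated decay genes 4 fell (4 adjusted over the list alone, median -0.12), led by NBAS (-1.35), which also acts in membrane traffic. The calls of the last pair of lists were lost otherwise (adjusted p = 0.0507 and adjusted p = 0.121 with an estimated correlation). The negative regulators of RAS, mTORC1 and JAK-STAT signalling ranked above other genes (camera adjusted p = 0.0281, adjusted p = 0.12 with an estimated correlation) although 2 of 26 fell, with SOCS3 at -0.85, and 1 rose (2 and 4 adjusted over the list alone, median 0.00). The 365 olfactory receptors, a control list, also ranked above other genes (camera adjusted p = 0.00443, adjusted p = 0.117 with an estimated correlation) while their median was -0.02 and 0 passed the target test (0 adjusted over the list alone). No shift was called for CCR4-NOT, decapping and cytoplasmic decay (4 of 31 fell, 5 adjusted over the list alone, median -0.13, CNOT1 at -1.80) or stress granule proteins (2 of 27 fell, 2 adjusted over the list alone, median -0.07, UBAP2L at -0.70). Nor was one called for the integrated stress response (1 of 17 fell, 1 adjusted over the list alone, median -0.08) or RIG-I-like receptor signalling (0 of 18, 0 adjusted over the list alone, median -0.06). The camera adjusted p of these lists were 0.128, 0.876, 0.124 and 0.699. The integrated stress response gene that fell, ATF5 (-2.27), lies within 1000 bp of NUP62 (-3.14).

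In the sgDDX3 arm the same kinds of genes were lost, with smaller effects, and guides against TRIM28 and EEF1A1 gained. The lowest growth effects were those of SMU1 (-3.23 ± 0.35), C12orf60 (-2.98 ± 0.33), the replication protein RPA2 (-2.90 ± 0.40), the splicing factor SF3A1 (-2.77 ± 0.33), NRDE2 (-2.73 ± 0.42) and the splicing factor CDC5L (-2.72 ± 0.22). GATA1 stood at -2.47 ± 0.17. The genes C12orf60, NRDE2 and SF3A1 lie within 1000 bp of WBP11 (-3.22 in the sgGal4 arm), PSMC1 (-2.89) and CCDC157 (-3.47). Whether their start sites are as close was not measured. The highest were TRIM28, the corepressor of KRAB zinc finger proteins (1.34 ± 0.16, limma adjusted p = 0.00116), the translation elongation factor EEF1A1 (0.92 ± 0.11, limma adjusted p = 0.00115), TXNIP, which restrains glucose uptake (0.76 ± 0.13), HIST1H2BE (0.73 ± 0.11), KCNN4 (0.71 ± 0.15) and LRRCC1 (0.71 ± 0.16). Of these calls, those of KCNN4 and LRRCC1 did not hold in 12 of 24 and 12 of 23 alternative settings, and KCNN4 stood at 0.07 with the median over guides. Those of TXNIP and HIST1H2BE were lost in 4 of 24 each, that of TRIM28 in 1 of 24 and that of EEF1A1 in 0 of 24. In the sgGal4 arm TRIM28 was at -0.01 and EEF1A1 at -0.02. The gene CHMP2A, whose annotated span lies within 1000 bp of that of TRIM28, was at -3.53 there.

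In all, 497 targets fell and 69 rose in the sgDDX3 arm (limma). The split moved with the scaling, to 400 and 121 with DESeq2 size factors, 484 and 80 with TMM and 746 and 47 by total count. Random sets of 5 non-targeting guides, of which 12.2% had an unadjusted p under 0.05, give 10.3 false losses and 41.0 false gains as the number to allow for. These numbers are rough, since they rest on 1 and 4 of 2000 sets. Fitted alone, without the quieter sgGal4 libraries, this arm gave 112 losses and 2 gains, those of TRIM28 and EEF1A1. Leaving out a library gave from 19 calls (without replicate 1 of the initial sgDDX3 group) to 4175 (without replicate 2 of the final sgDDX3 group).

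The loss of translation and splicing genes also held as lists in the sgDDX3 arm. With both settings of the correlation, lower shifts were found for the large (23 of 47 fell, 39 adjusted over the list alone, median -0.76, RPL6 at -2.31) and small (14 of 32, 25 adjusted over the list alone, median -0.65, RPS4X at -1.48) ribosomal subunit proteins. They were also found for the small-subunit processome (8 of 47, 18 adjusted over the list alone, median -0.35, PDCD11 at -1.08), eIF3 (5 of 13, 9 adjusted over the list alone, median -0.63, EIF3A at -1.81) and the aminoacyl-tRNA synthetases (6 of 20, 11 and 3 higher adjusted over the list alone, median -0.45, SARS at -2.04). The ternary complex, subunit joining and elongation list also shifted lower, with 3 of 25 lower and EEF1A1 higher (7 and 1 adjusted over the list alone, median -0.23, EIF2S1 at -1.52). The same held for the spliceosome core (34 of 56, 45 and 1 higher adjusted over the list alone, median -0.99) and the 26S proteasome (10 of 32, 17 adjusted over the list alone, median -0.48, PSMC4 at -1.68 and PSMD7 at -1.43). It held as well for DNA replication (18 of 49, 32 adjusted over the list alone, median -0.62, GINS1 at -2.09) and the nuclear pore complex (8 of 30, 13 adjusted over the list alone, median -0.27, NUPL1 at -2.32). Further lists were TREX, the exon junction complex and mRNA export (8 of 35, 14 and 2 higher adjusted over the list alone, median -0.28, THOC2 at -1.33) and 3-prime end processing (3 of 35, 11 adjusted over the list alone, median -0.22, INTS2 at -1.28). INTS2 stood at -1.89 and -0.66 in replicates 1 and 2, and its call was lost in 9 of 24 alternative settings. Condensin and cohesin (6 of 21, 10 adjusted over the list alone, median -0.35, SMC1A at -1.14), the mTORC1 activators (5 of 24, 8 adjusted over the list alone, median -0.24, MTOR at -1.27) and the BCR-ABL list (5 of 36, 11 adjusted over the list alone, median -0.22) completed the 15 lists that held under both settings.

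A further 5 lists in the sgDDX3 arm were called with the preset correlation alone. They were the mitochondrial ribosomal proteins (3 of 75 fell, 16 adjusted over the list alone, median -0.27, MRPL10 at -0.70) and the nuclear exosome list (3 of 26, 6 adjusted over the list alone, median -0.24, SRRT at -0.95). With them went the DEAD-box helicases (5 of 38, 9 and 1 higher adjusted over the list alone, median -0.16, EIF4A3 at -1.25), respiratory complex I (1 of 50, 2 adjusted over the list alone, median -0.16, NDUFA2 at -0.67) and, upward, the negative regulators of RAS, mTORC1 and JAK-STAT signalling. In the order given, these had adjusted p = 0.105, adjusted p = 0.0839, adjusted p = 0.0759, adjusted p = 0.104 and adjusted p = 0.0759 with an estimated correlation. Of the 26 negative regulators 3 rose (5, and 1 lower, adjusted over the list alone, median 0.12), with CBL, a ubiquitin ligase that dampens receptor signalling, at 0.54 ± 0.09. No shift was called in this arm for eIF4F (2 of 15 fell, median -0.04, EIF4G2 at -1.68), nonsense-mediated decay (1 of 13, median -0.15, SMG5 at -0.57) or cytoplasmic decay (0 of 31, median -0.05). None was called for stress granules (0 of 27, median -0.10), the integrated stress response (1 of 17, median -0.04, ATF5 at -1.47), RIG-I-like receptor signalling (0 of 18, median -0.02), ribosome quality control (1 of 18, median -0.08, PELO at -0.74) or olfactory receptors (2 of 365 rose, median -0.04, OR7E24 at 0.55). Adjusted over the list alone, these had 3, 2, 0, 3, 1, 0, 1 and 0 lower and, in eIF4F, 1 higher, and their camera adjusted p ran from 0.151 to 0.858.

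**Figure D2:**
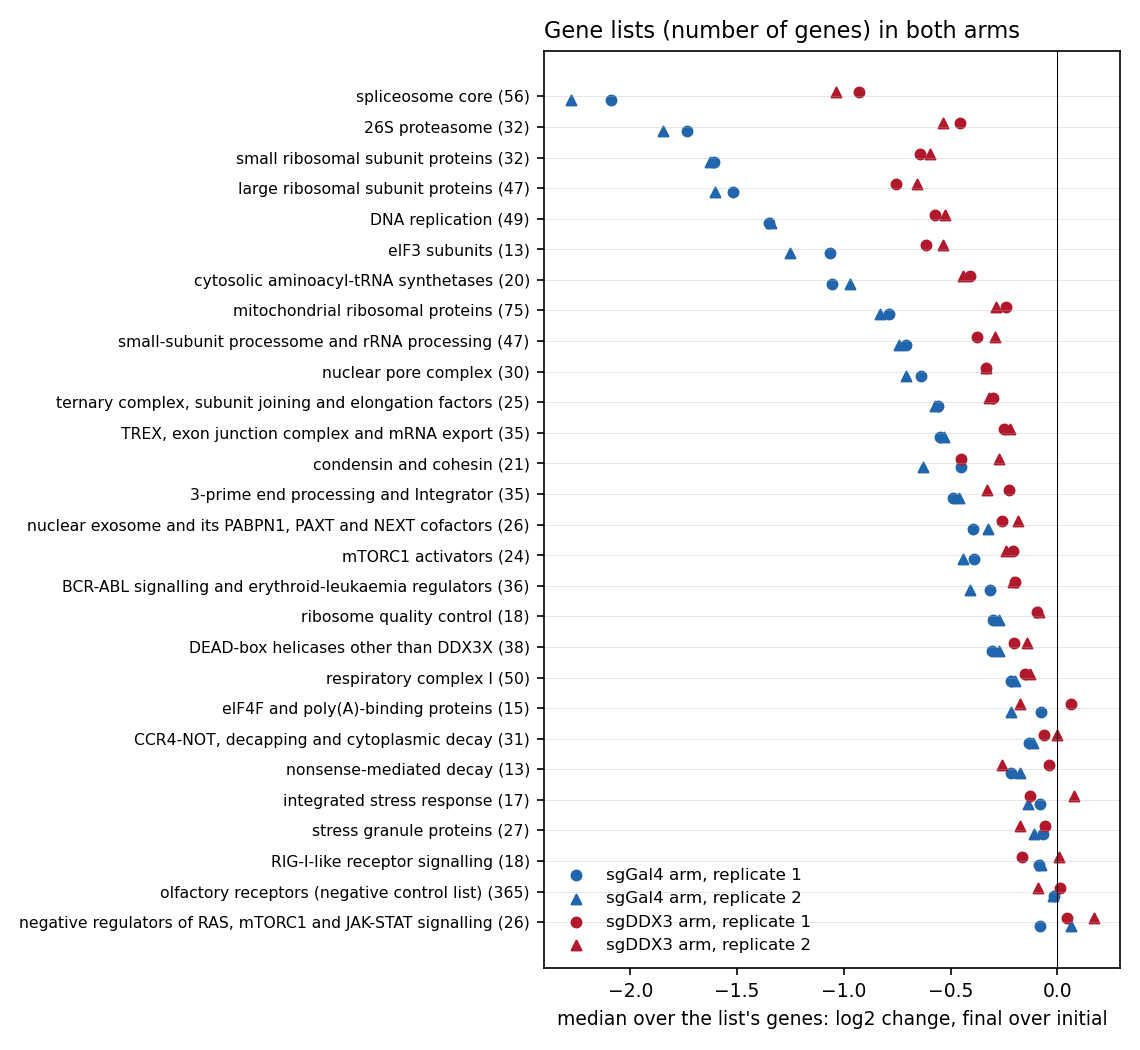
Median growth effect (log2, final over initial) of the genes of each of 28 lists, with the number of genes in parentheses, for replicates 1 and 2 (circles and triangles) of the sgGal4 arm in blue and the sgDDX3 arm in red. The spliceosome core lies lowest, at a median of -2.23 in the sgGal4 arm and -0.99 in the sgDDX3 arm.

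Most targets lost in the sgDDX3 arm were also lost in the sgGal4 arm. Of the 497 and 1420 targets called lower, 412 were shared, against 34.4 for independent lists of those sizes, and LZTR1 and ARRDC3 were the 2 higher in both, against 0.0269. The arms have no library in common, but both tests used the same pooled spread of each target. The numbers for independent lists are therefore a loose reference. Across primary targets, which are not independent replicates, the effects correlated with r = 0.601. Over 137 genes of the proteasome, spliceosome and replication lists, sgDDX3 effects were 0.488 times the sgGal4 effects (bootstrap 95% interval 0.445 to 0.529, resampling genes), which covers the spread between genes and not between libraries.

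**Figure D3:**
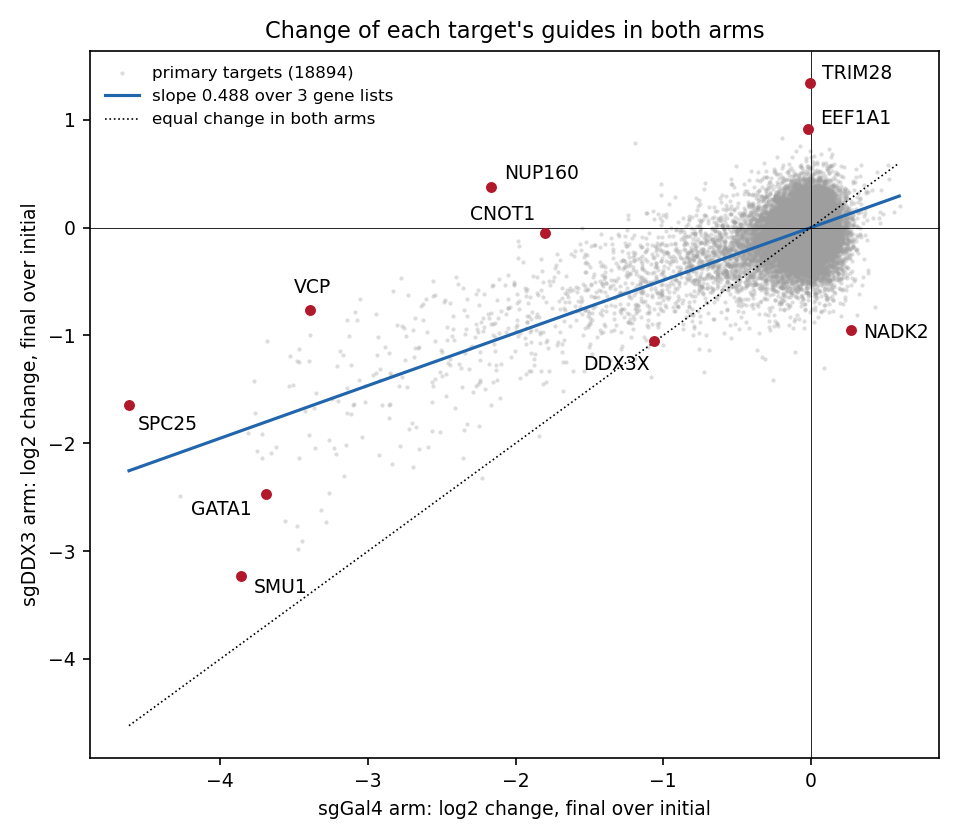
Growth effect (log2, final over initial) of 18894 primary targets in the sgGal4 arm (horizontal) and the sgDDX3 arm (vertical), with the slope of 0.488 over 3 gene lists in blue, equal change dotted and 10 genes named in red. SPC25 lies at -4.62 and -1.65, and TRIM28 at -0.01 and 1.34.

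Without allowing for that scale, 316 targets were higher and 2 lower in the sgDDX3 arm (limma). Of the 316, 306 had been called lower in the sgGal4 arm and 49 stood above 0 in the sgDDX3 arm. The largest differences were those of SPC25 (2.97 ± 0.37), HMGCS1, a sterol synthesis enzyme (2.63 ± 0.32), VCP (2.63 ± 0.37) and the nuclear pore protein NUP160 (2.54 ± 0.34). Each of these calls was lost in 5 of 23 alternative settings, with lowest values of 2.394, 1.528, 1.075 and 1.876 in that order. NUP160 was at -2.16 in the sgGal4 arm and 0.37 in the sgDDX3 arm, where it was not called (limma adjusted p = 0.446). CNOT1, the scaffold of the CCR4-NOT deadenylase, was at -1.80 and -0.05 (difference 1.75 ± 0.26, limma adjusted p = 0.00718), and NBAS at -1.35 and -0.09 (1.26, limma adjusted p = 0.0139). The 2 lower targets were the mitochondrial NAD kinase NADK2 (-1.22 ± 0.27) and SLC25A26, which carries S-adenosylmethionine into mitochondria (-0.77 ± 0.15), each read by 4 guides. TRIM28 (1.35, limma adjusted p = 0.0114), EEF1A1 (0.94, limma adjusted p = 0.0102) and TXNIP (0.83, limma adjusted p = 0.0472) were higher in the sgDDX3 arm in this test of the difference as well. The count was 0 when any 1 of the 4 initial libraries was left out, 138 or 139 without a final sgGal4 library, and 1889 or 2148 without replicate 1 or 2 of the final sgDDX3 group, where the lone library left is assumed to vary like the others. The call of NADK2 was lost in 16 of 23 alternative settings.

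As lists, 20 of 28 ranked higher than other genes by camera in the difference of the sgDDX3 from the sgGal4 arm without the scale, 16 of them also with an estimated correlation. The 26S proteasome (median 1.17, 17 of 32 higher, 28 adjusted over the list alone), spliceosome core (0.90, 20 of 56, 43 adjusted over the list alone), small (0.88, 9 of 32, 28 adjusted over the list alone) and large (0.81, 11 of 47, 29 adjusted over the list alone) ribosomal subunit proteins led. DNA replication (0.68, 7 of 49, 34 adjusted over the list alone), aminoacyl-tRNA synthetases (0.67, 6 of 20, 17 adjusted over the list alone) and mitochondrial ribosomal proteins (0.56, 12 of 75, 41 adjusted over the list alone) followed. The olfactory receptors were the list that shifted lower (median -0.04, adjusted p = 0.187 with an estimated correlation), with OR7E24 higher (0.69).

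With the scale allowed for, 0 targets differed between the arms by limma with all 8 libraries. In this test each sgDDX3 effect was compared with 0.488 times the sgGal4 effect. Limma gave 2248 of 20514 targets at an unadjusted p under 0.05 and 0 after adjustment, and 9.15% of random sets of 5 non-targeting guides were also under 0.05 before adjustment. Of the other tests, edgeR on summed counts gave 3, DESeq2 on summed counts 368 and the Mann-Whitney test 0. TRIM28 (1.35 ± 0.17) and EEF1A1 (0.93 ± 0.12) came closest, both at an adjusted p of 0.0674, and passed in some of the alternative settings. The count was 2035 or 2380 without replicate 1 or 2 of the final sgDDX3 group, where the lone library left is assumed to vary like the others, and 0 without any 1 of the other 6 libraries. DDX3X was at -0.54 ± 0.16 (limma adjusted p = 0.301). In simulated data, limma called 70% of targets with a true scaled difference of 1 or -1. It called 0% of those at 0.5 and 10% of those at -0.5, so differences of the smaller size were mostly not detectable with these libraries. The simulation gave each group a single spread, changed all guides of a target alike and took the slope as known. The 70% may therefore not carry over, and differences near 1 may have been missed as well. Lists that lay above the common scale were the 26S proteasome, which is among the 3 lists that set the scale (median 0.33, 7 of 32 below 0, 5 higher adjusted over the list alone), the small ribosomal subunit proteins (0.11) and the mitochondrial ribosomal proteins (0.14), with 0 higher adjusted over the list alone in the last pair. None of these calls held otherwise (adjusted p = 0.183, adjusted p = 0.335 and adjusted p = 0.565 with an estimated correlation). None of the remaining lists passed, including DEAD-box helicases (median 0.02), eIF3 (0.05), TREX and mRNA export (0.05), stress granule proteins (-0.06) and nonsense-mediated decay (-0.09), with 0 members of each past the target test. Adjusted over the list alone, eIF3 had 1 lower and 1 higher and TREX had 1 lower and 3 higher, with 0 in the others named here.

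At the initial time point 0 targets differed between the arms (limma, 119 at an unadjusted p under 0.05, and 0 by edgeR, DESeq2 and Mann-Whitney), and the median difference over all targets was 0.01. The limma test is conservative here, since its shared spread takes in the wider final libraries. The SD of target scores between replicates was 0.096 and 0.103 in the initial sgDDX3 and sgGal4 groups and 0.257 in the final sgDDX3 group. Of random sets of 5 non-targeting guides 0.4% were under 0.05 before adjustment.

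Guide by guide, edgeR called 3181 guides lower and 3 higher in the sgGal4 arm (1 of CBL and 2 of CDKN1C), and 551 lower and 126 higher in the sgDDX3 arm, of 102179. In the sgDDX3 arm TMM gave 420 lower and 207 higher, and DESeq2 called 4315 guides. Leaving out a library gave from 1 guide there (without replicate 1 of the initial sgDDX3 group) to 19888 (without replicate 2 of the final sgDDX3 group). The guides of TRIM28 took part in the gain unevenly, with 4 of 5 between 0.71 and 2.47 and the other at 0.08, and those of EEF1A1 ran from 0.23 to 1.95. Between arms without the scale, 137 guides were higher and 0 lower (8814 at an unadjusted p under 0.05, and 1136 called by DESeq2). Of 1841 non-targeting guides, 1, 3 and 0 were called in the sgGal4, sgDDX3 and between-arm tests. The 1 in the sgGal4 arm was lower, and the 3 in the sgDDX3 arm were all higher, 0.163% of non-targeting guides. The 126 gains among 102179 guides in the sgDDX3 arm are not a larger share than that.

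The authors' deposited tables give DDX3X -1.37 in the sgGal4 arm and -1.64 in the sgDDX3 arm as the mean of the strongest 3 guides, with Mann-Whitney p-values of 0.000709 and 0.00683. In the authors' deposited table of the sgDDX3 arm TRIM28 stands at 2.00 and EEF1A1 at 1.33, and in that of the sgGal4 arm at -0.05 and -0.06. Across targets, the authors' deposited values and the growth effects reported here correlated with r = 0.966 in the sgDDX3 arm and 0.982 in the sgGal4 arm.

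**Figure D4:**
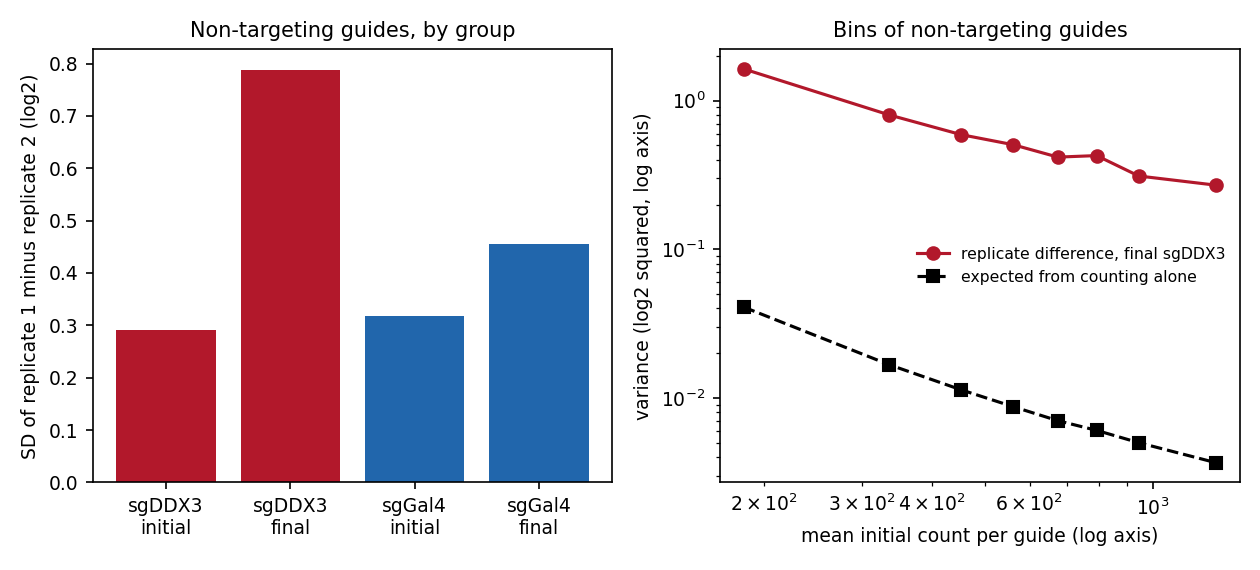
Left, SD of the difference between replicates 1 and 2 (log2) over non-targeting guides in each group, sgDDX3 in red and sgGal4 in blue; right, variance of that difference in the final sgDDX3 libraries (red) and the variance expected from counting alone (black, dashed) in bins of non-targeting guides by mean initial count, on log axes. The final sgDDX3 libraries reach 0.788, and their variance lies above counting noise in all 8 bins.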

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

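The comparison of depths between the final groups and that of TRIM28 and EEF1A1 with random guide sets were chosen after the results were seen, as was the setting with a spread of its own for each group, and the other tests in this part were set before theirs were.

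Effects were smaller in the sgDDX3 arm, at 0.488 times those of the sgGal4 arm over 3 lists, and cells that escaped silencing there would blunt strong effects more than weak ones. The ratio of sgDDX3 to sgGal4 effects was 0.487 in the 221 targets that fell below -2 in sgGal4 replicate 1 and 0.450 in the 897 between -1 and -0.5 (sgGal4 effects from replicate 2). The quotient of 1.08 (95% interval 0.999 to 1.17, resampling targets and not libraries) argues against such escape under the non-targeting scaling. It was not computed with other scalings. Scaling by total count moved the median of all targets from -0.04 to 0.02 in the sgGal4 arm. In the sgDDX3 arm that median went from -0.05 to -0.10. The pseudocount and low counts do not account for the smaller effects either, since the slope rose by at most 0.00232 with a pseudocount of 0.1 or a minimum count of 200. The same quotient of 1.08 is consistent with a common scale, as fewer doublings between the sampled time points would give. Slower growth of cells with DDX3X targeted, a shorter interval and evenly weaker silencing all stay open and were not tested, as the doublings are not given in the sources used here.

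The final sgDDX3 libraries differed from each other most, with an SD over non-targeting guides of 0.788 against 0.455 in the final sgGal4 libraries. Sequencing depth does not account for this, since the shallower final sgDDX3 library (63666770 counts) had 0.939 times the counts of the deeper final sgGal4 library (67805763). The variance fell with guide abundance, from 1.63 in the bin with a mean initial count of 183.8 to 0.270 in the bin with 1299. After the counting variance was taken off, its slope on log axes was -0.892 (95% interval -1.01 to -0.773), which is consistent with few cells or template molecules carried per guide. Whether that happened in culture or before the PCR cannot be read from these counts, and no biological explanation was tested.

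Guides against TRIM28 and EEF1A1 gained in the sgDDX3 arm by 1.34 and 0.92, and of 100000 random sets of 5 non-targeting guides 0 rose as far as the lower gene, which argues against drift. Nor is a single aberrant guide likely, since 3 of 5 guides of each gene rose by more than 0.82, the upper end of the central 95% of non-targeting guides. TRIM28 is the corepressor through which KRAB repressors silence, and its loss could release the DDX3X knockdown. The median scaled difference of 9 cofactors of that silencing was -0.01, at percentile 47.9 among 10000 random lists. Of them 3 were above 0, SETDB1 stood at 0.00 and MORC2, the lowest, at -0.61. A loss of the silencing would raise that median only if most of the 9 were each needed for it. Whether they are was not measured, so the median does not decide the question. That release stays open, as does a step that needs TRIM28 more than the cofactors (CBX1, CBX3 and CBX5 can replace each other). For EEF1A1, whose promoter is widely used in expression constructs, an effect on the repressor itself also stays open. The latter pair were not tested. For EEF1A1 the constructs' promoters, which such a test would need, are not given in the sources used here. The scaled difference of both genes missed the threshold by limma (adjusted p = 0.0674) but passed with a curved scale (adjusted p = 0.0222 for both), a spread of its own for each group (4.12e-06 for TRIM28 and 0.00742 for EEF1A1) and edgeR on summed counts (0.00125 and 0.00858), and that of TRIM28 with the median over guides (0.00377), while the sgDDX3 call of TRIM28 was lost without replicate 1 of the initial sgDDX3 group (adjusted p = 0.0591).

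The test of the difference between the arms' effects without the scale called 316 targets higher and 2 lower. Only those among the genes named by the rule are given here, as sgDDX3 minus sgGal4. Many of them were named for a large loss in the sgGal4 arm. Higher were SPC25 (2.97), HMGCS1 (2.63), VCP (2.63), NUP160 (2.54), AURKB (2.35), RBM8A (2.24), NUP205 (2.04), PSMB6 (1.84), CNOT1 (1.75), PSMC4 (1.69), CSTF1 (1.49), NDUFA2 (1.45), SMC2 (1.42), MRPL16 (1.40), SMC1A (1.37), NBAS (1.26), GATA1 (1.22), EIF4A3 (1.20), DDX23 (1.20), MRPL13 (1.17), FBL (1.00) and EXOSC2 (0.79), all of which had fallen in the sgGal4 arm. Also higher were TRIM28 (1.35), EEF1A1 (0.94), TXNIP (0.83) and OR7E24 (0.69), which had not fallen there, and lower were NADK2 (-1.22) and SLC25A26 (-0.77).

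By camera, which compares a list with the other genes, these lists shifted in the difference between the arms without the scale, and their medians are given. They were the 26S proteasome (1.17), spliceosome core (0.90), small (0.88) and large (0.81) ribosomal subunit proteins, DNA replication (0.68), cytosolic aminoacyl-tRNA synthetases (0.67), eIF3 (0.59), mitochondrial ribosomal proteins (0.56), small-subunit processome (0.50), TREX and mRNA export (0.35), nuclear pore complex (0.34), 3-prime end processing and Integrator (0.34), ternary complex and elongation factors (0.34), DEAD-box helicases (0.28), condensin and cohesin (0.23) and the BCR-ABL list (0.19), which held with an estimated correlation. With the preset correlation alone they were eIF4F (0.24), ribosome quality control (0.21), mTORC1 activators (0.19), the nuclear exosome list (0.16) and, lower, the olfactory receptors (-0.038). With the scale, the 26S proteasome (0.33), small ribosomal subunit proteins (0.11) and mitochondrial ribosomal proteins (0.14) lay higher with the preset correlation alone.

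Of the counts, 0.627% to 0.652% per library fell on guides outside the library table. Of 104535 such guides 956 had a count and 671 a mean of at least 50, and 646 of these had counts equal to those of a library guide in all 8 libraries. Guides with such equal counts held 98.9% of the counts outside the table.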

How the results depend on the processing

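The fit with a spread of its own for each group, that of an arm's 4 libraries alone and the 5-guide pseudo-genes were chosen after the data were seen, and the other settings before. Of 102 gene results, 51 kept their side of the threshold in every setting tried, 50 lost their call in at least 1 setting, and 0 called results reversed direction. The other, the scaled difference of DDX3X, passed without replicate 2 of the final sgDDX3 group (-0.61, adjusted p = 0.0156) and in no other setting. Most losses came without an initial sgDDX3 library (45 without replicate 1, 40 without replicate 2), with the median over guides (25), without an initial sgGal4 library (19 and 22) and with an arm fitted alone (21). The call of DDX3X in the sgDDX3 arm was lost in 4 of 24 settings and that of EEF1A1 there in 0 of 24. Among the 51 results, the uncalled unscaled and initial differences of DDX3X changed sign between settings. They ran from -0.11 to 0.36 and from -0.09 to 0.14. The setting with only the 5 guides the library ranks first was not run, since the library table holds no more than 5 guides per target.

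Against 1428 calls for the sgGal4 growth effect and 566 for the sgDDX3 growth effect, the median over guides gave 937 and 202. The sgDDX3 growth effect also gave 371 calls with a spread of its own for each group, 114 from that arm alone, 222 by Mann-Whitney and 1703 by DESeq2 on summed counts. The unscaled difference between arms (318) gave 173 by total count, 90 by the median over guides and 683 by DESeq2 on summed counts. Scaling by total count moved the median of all targets for that difference from 0.03 to -0.08. The scaled difference between arms (0) gave 2 with the median over guides, 2 with a curved scale, 3 with a spread of its own for each group, 3 by edgeR on summed counts and 368 by DESeq2 on summed counts. TRIM28 was among each of the first 4 sets. It was joined by C6orf1 with the median, by EEF1A1 in the other 3, by PRMT5 with a spread of its own for each group and by GATM with edgeR, and these genes were chosen after their values were seen. The initial difference between arms (0) gave 2, CENPA and SLC35F6, with a spread of its own for each group. Both targets had the same estimate (0.438) and the same adjusted p, so they may not be separate measurements. For guides, DESeq2 gave 4315 against 677 for the sgDDX3 growth effect and 1136 against 137 for the unscaled difference between arms. The slope between arms was 0.566 over all primary targets and 0.431 as the median ratio, against 0.488. Of the 3 gene lists above the common scale, 0 passed with an estimated correlation. The cause of these changes was not tested.

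A replicate block within each arm gave 1054 calls for the sgDDX3 growth effect, 524 for the unscaled difference between arms and 2 for the scaled difference between arms (TRIM28 and EEF1A1), and for guides 1446 and 315. A block shared by both arms gave 1 for the scaled difference between arms (TRIM28). Replicate deviations of the initial and final libraries correlated with r = 0.215 in the sgDDX3 arm and 0.353 in the sgGal4 arm, and across arms with 0.000127 at the final and 0.00877 at the initial time point. This is a hint of pairing within arms from the data, but with 2 pairs per arm and no such statement in the labels the numbers were not taken to pair the libraries.

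Leaving out 1 library, with the lone library left assumed to vary like the other groups, gave 873 to 2196 calls for the sgGal4 growth effect, 19 to 4175 for the sgDDX3 growth effect, 0 to 2380 for the scaled difference between arms and 0 to 2148 for the unscaled difference between arms. For guides the ranges were 1295 to 5769 for the sgGal4 growth effect (3184 with all 8 libraries), 1 to 19888 for the sgDDX3 growth effect and 0 to 8484 for the unscaled difference between arms. The slope between arms ran from 0.481 to 0.499. The highest counts of targets came without replicate 2 of the final sgDDX3 group, whose 2 libraries differ most, so that leaving out either removes the widest spread from the pooled estimate.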

Other observations

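The genes in this part were chosen after their values were seen. In the sgGal4 arm guides against BCR fell by 2.96 and those against ABL1 stood at -0.07 (limma adjusted p = 1.00), and in the sgDDX3 arm at -1.36 and -0.08. K562 carries the BCR-ABL fusion, which is transcribed from the BCR start site. Among the elongation factors, EEF1A1 stood at -0.02 in the sgGal4 arm and EEF2 at -1.89, while STAT5B, a mediator of BCR-ABL signalling, fell by 1.33 there.

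Some genes lost in the sgGal4 arm had estimates above 0 in the sgDDX3 arm. They were the arginine methyltransferase PRMT5 (-1.02 and 0.40, limma adjusted p of the unscaled difference 0.00823), TRAPPC11 of a vesicle tethering complex (-1.01 and 0.31, limma adjusted p = 0.00635) and NUP160 (-2.16 and 0.37, limma adjusted p = 0.0054). With the scale the differences were 0.90, 0.80 and 1.43, each at an adjusted p of 0.255. At the other end, FLVCR1, a haem exporter read by 3 guides, was at -0.26 in the sgGal4 arm and -1.41 in the sgDDX3 arm (scaled difference -1.29, limma adjusted p = 0.318), and EIF2S3, a subunit of the initiation factor that forms the ternary complex, at -0.72 and -1.34 (-0.99, limma adjusted p = 0.255).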
